A study of Xenopus laevis with 8 samples.

How the data were processed

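RNA from 8 pools of stage 27 Xenopus laevis eyes was labelled with Cy3 and hybridised to Agilent 1-colour arrays, per the labels' protocols. The deposited scanner files were made with Agilent Feature Extraction 10.5.1.1, per the file headers and the submitters' processing notes. Each array holds 45220 spots, of which 43803 are gene spots of 43653 probes of 60 bases. The processed signal is an intensity on a linear scale that the software had background-subtracted and detrended within each array, per the file headers, with no scaling between arrays. The mean spot intensity and the median local background intensity in the same files are raw brightness, per the file headers. The flags for spots above background, saturation and outliers are the software's own, per the file headers. The authors' value table holds log2 values, and a comparison with the scanner files showed that each column is the log2 processed signal shifted to a median of 7.51. At least 99.98% of values lay within 0.01 of the column's offset. A genome build is not given in the sources used here, and no coordinates are reported.

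Samples were grouped by the treatment in their titles, 4 Ezh2 morpholino and 4 control morpholino. The main values were the log2 processed signal minus each array's 75th percentile, plus the mean of those percentiles over arrays. Control spots and outlier spots (1 to 9 gene spots per array) were left out, and repeat spots of a probe were averaged on the log2 scale. A probe was tested when it was well above background on at least 4 of the 8 arrays, which kept 36825 probes (84.4%). Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with the data.table package (version 1.17.8), and p-values were adjusted by Benjamini-Hochberg over all probes tested, with a threshold of 0.05. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The median log2 change over all probes tested was 0.05 in the main values and 0.12 with normexp, and it depended on brightness, from 0.17 for probes with a mean log2 signal near 5.01 to -0.07 near 15.5. Where a probe was not above background on any array of a group, the fold is given as "at least": the bright group's mean against the dim group's mean, with each dim array set to the lowest signal of its probes well above background where the probe lay below it.

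Probes were named through RefSeq gene records of assembly Xenopus_laevis_v10.1. Of 17400 probes with a RefSeq mRNA accession, 16039 matched by accession, 447 probes matched by gene identifier, 954 by symbol and 109 by an older symbol. A further 1398 matched a symbol for which the file does not say which homeolog is meant. The file's own name was kept for 851 probes. In all 18697 probes carry a gene symbol, of 11802 genes, and other probes are given by their array name. Where a gene had several passing probes, the brightest stood for it, and probes of a named gene that changed in the opposite direction are given beside it. Homeologs are close in sequence, so a probe may take up signal from both copies.

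Before the data were examined, 24 gene lists were fixed from textbook knowledge. Lists were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry, and adjusted over the 24 lists. None of the 24 lists passed an adjusted p of 0.05 with the estimated correlation. The named genes follow a rule fixed at the same time. It takes all measured PRC2 subunits and Cdk inhibitors, then the 10 largest rises and 10 largest falls past the threshold whose 4 Ezh2 morpholino arrays lie on 1 side of all 4 control arrays, filled up by smallest p, and up to 4 members with the smallest p from each other list. Within that limit, up to 4 members were taken from called lists and from lists bearing on the question, and 2 from the rest. This split was not part of the fixed rule and depended on which lists were called.

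On simulated arrays with the real probes' means and spreads over 36825 probes, 4 against 4, 38 of 100 planted log2 changes of 1 and 86 of 100 planted changes of 2 were recovered, with 5 false calls. A list with a planted change was called and 0 of the other lists. The simulation took over means and spreads of single probes, so it does not test lists whose genes vary together. The estimated correlation within the real lists ran from 0.012 for regulators of non-eye lineages to 0.637 for Cdk inhibitors. On the real arrays, 25 of 35 splits into groups of 4 called at least as many lists as the real split. Slide was examined as a batch: each slide holds 1 group, so neither a slide block nor a scan date block could be fitted, and slide and group cannot be told apart. The alternatives were normexp (offset 50) on mean and background signals, quantile normalization, median scaling, no filter, a filter on all 8 arrays, the authors' value table, a replicate block, an intensity trend with robust estimates, array weights, leaving out each array, a 1.5-fold minimum, and for lists the estimated correlation and the mean over a gene's probes. An alternative without Ezh2 morpholino replicates 1 and 3 was chosen after seeing the data.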

Results

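Gene expression was measured in dissected eyes of Xenopus laevis, an African clawed frog with a duplicated genome in which most genes have an L and an S copy (homeologs). Embryos had received 5 ng of a morpholino at the 8-cell stage together with 400 pg of GFP mRNA as a tracer of the injected cells, and GFP-positive eyes were collected at stage 27. A morpholino is a synthetic antisense oligomer, and the one used here covers the start codon of Ezh2, the histone H3 lysine 27 methyltransferase of Polycomb repressive complex 2 (PRC2); the control morpholino carries a scrambled order of the same bases. Each of the 8 arrays was hybridised with RNA from its own pool of 20 to 25 eyes, 4 pools with the Ezh2 morpholino and 4 with the control morpholino. The labels do not say whether the pools came from different parents, so the p-values measure the spread between these pools. The 75th percentile of the processed signal ranged from 1258 to 1835 between arrays, 80.5% to 85.5% of gene spots lay well above background, and no gene spot was saturated. The number of arrays limits the precision. All 4 Ezh2 morpholino arrays lay on 1 slide and all 4 control arrays on the other, so slide and group cannot be told apart in any comparison given here. On the first principal component, which held 27.7% of the variance, Ezh2 morpholino replicates 1 and 3 lay at -74.3 and -55.3 and the other 6 arrays between -14.7 and 55.2.

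The title of the series asks what PRC2 does for proliferation and neurogenesis in the retina, and the first measurement concerns the targeted gene. The ezh2 mRNA did not pass the test in either copy. ezh2.L, among the brighter probes, had a log2 signal of 15.02 ± 0.06 (SD, n = 4) in Ezh2 morpholino eyes and 15.25 ± 0.11 (SD, n = 4) in control eyes, a log2 change of -0.23 with a standard error of 0.11 and an adjusted p of 0.361 (limma). The other ezh2.L probe gave -0.21 (adjusted p = 0.397). ezh2.S had a log2 change of -0.06 with a standard error of 0.13 (adjusted p = 0.859). A morpholino of this kind blocks translation, so the mRNA level says nothing about the protein and does not check the labels. A label field of the Ezh2 samples also carries the word siRNA beside morpholino; an siRNA would act on the mRNA itself, and for it the mRNA level would bear on the labels. None of the 13 measured PRC2 genes, each by its brightest probe, passed the test, over all probes or adjusted over the list alone. The core subunits eed.L and eed.S had log2 changes of -0.24 and -0.22, suz12 of 0.15, and the histone-binding subunits rbbp4.S and rbbp7 of -0.05 and -0.15. The probes of eed.S disagreed: the other one, of nearly equal brightness, gave 0.43 (SE 0.13, adjusted p = 0.217). Dimmer probes of rbbp4.S and rbbp7 gave 0.04 and 0.05. The list's median was -0.06, and camera, a test of a list against all other genes, gave an adjusted p of 0.173, though the list passed with normexp and its median ranged from -0.15 to 0.04 over the alternatives. In the main values, random lists of the same brightness had a median of -0.042 (95% range -0.182 to 0.103). The PRC2 list thus did not stand apart from genes of its brightness.

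Few single probes passed the adjusted threshold. Of 36825 probes tested, 11 were higher and 1 was lower in Ezh2 morpholino eyes at an adjusted p under 0.05 (limma, Benjamini-Hochberg), and 4 of these 12 carried a gene symbol. At an unadjusted p under 0.05 there were 5531 probes, where chance gives 1841. For 3606 probes (9.8%) all 4 Ezh2 morpholino arrays lay on 1 side of all 4 control arrays, where chance gives 2.86%. The probe with the smallest p belonged to fzr1.L, which encodes Cdh1, an activator of the anaphase-promoting complex that drives exit from mitosis. It rose from a log2 signal of 9.75 ± 0.13 (SD, n = 4) to 12.88 ± 0.17 (SD, n = 4), an 8.73-fold change (log2 3.13, SE 0.13, adjusted p = 0.000113). The other fzr1.L probe lay at 11.02 and 11.02, with a log2 change of -0.004 (SE 0.14, adjusted p = 0.992), so the rise belongs to 1 probe and not to every probe of the gene. The probe that rose has the sequence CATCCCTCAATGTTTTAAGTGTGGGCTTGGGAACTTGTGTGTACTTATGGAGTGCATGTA, and the other has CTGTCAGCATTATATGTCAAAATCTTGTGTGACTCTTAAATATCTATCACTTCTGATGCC.

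adhfe1.S, an iron-containing alcohol dehydrogenase of mitochondria, rose 7.51-fold (log2 2.91, SE 0.30, adjusted p = 0.0308) from 5.69 ± 0.30 to 8.60 ± 0.62 (SD, n = 4 each). spop.S, a substrate adaptor of Cullin 3 ubiquitin ligases, rose by a log2 change of 1.42 (SE 0.15, adjusted p = 0.0308) on 1 probe. Its brighter and overlapping probe gave 1.37 (SE 0.18, adjusted p = 0.071). dph1.L, an enzyme of diphthamide synthesis on elongation factor 2, fell by 0.91 on the log2 scale (SE 0.10, adjusted p = 0.0347), from 11.32 ± 0.06 to 10.42 ± 0.03 (SD, n = 4 each). Its other probe gave -0.68 (adjusted p = 0.152). The dph1.L call was lost without any 1 of the 8 arrays (limma adjusted p from 0.0900 to 0.147), at a log2 change of -0.93 to -0.88. The adhfe1.S call was lost without Ezh2 morpholino replicate 2 or 3 or any 1 control array (limma adjusted p up to 0.121), at a log2 change of 2.68 to 3.13 over all single arrays left out. The 8 remaining probes carry no gene symbol and are named here after their values were seen. They include A_10_P273227, annotated on the array as similar to the calcineurin inhibitor Cabin 1 (log2 change 2.17, adjusted p = 0.000597), and A_10_P258657, annotated as similar to junctional adhesion molecule 2 (1.75, adjusted p = 0.031). For 3 of the 8 the control eyes were not well above background on any array. For these the rise in the main values is a lower bound: at least 1.69-fold for A_10_P015490, at least 1.95-fold for A_10_P136223 and at least 3.17-fold for A_10_P106300. With normexp background correction the counts were 12 higher and 4 lower, with 8 of the 12 calls kept, with an intensity trend and robust variance estimates 16 higher and 4 lower, with all 12 kept, and leaving out 1 array at a time gave 5 to 9 higher and 0 to 2 lower. Without Ezh2 morpholino replicates 1 and 3 (an alternative chosen after seeing the data) 3 probes were higher and 0 lower, at 6 arrays in place of 8.

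**Figure D1:**
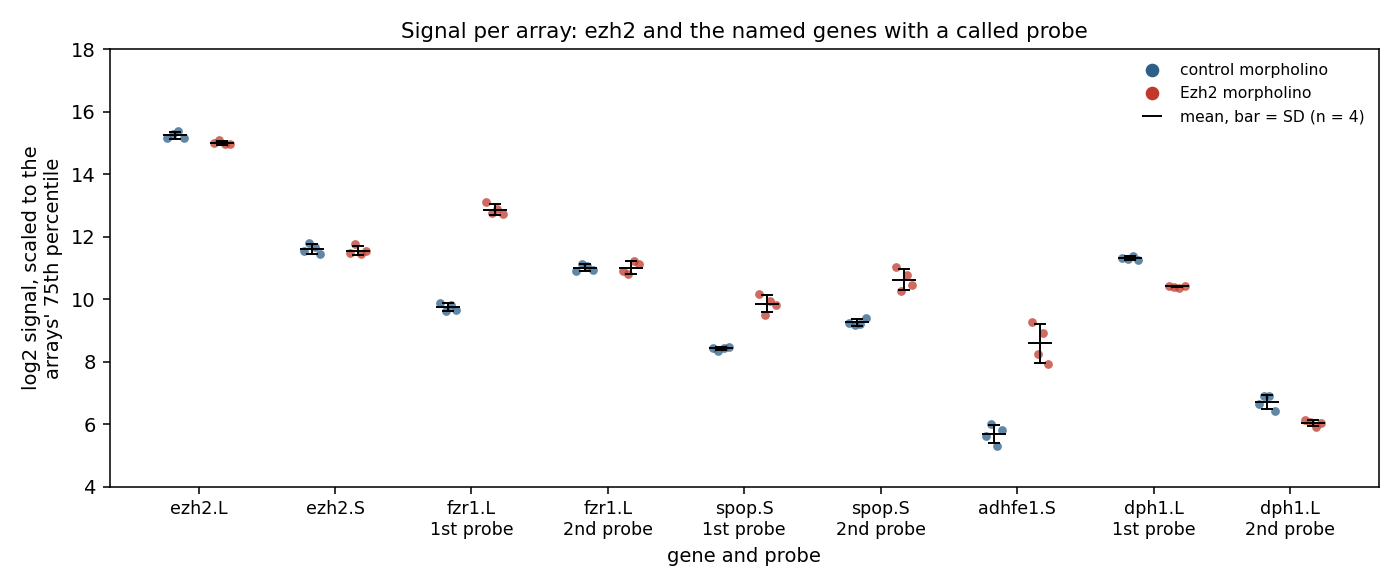
Each point is the log2 signal of 1 array, scaled to the arrays' 75th percentile, for ezh2 and for the named genes with a called probe; black marks give the mean and SD of the 4 control (blue) and 4 Ezh2 morpholino (red) arrays, and the 1st probe of a gene is the called one. The called fzr1.L probe lies at 9.75 in control and 12.88 in Ezh2 morpholino eyes on average, while the other fzr1.L probe lies at 11.02 in both.

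Further named genes with the smallest p did not pass the threshold. Above their control level were farp2.S (log2 change 1.65, SE 0.21, adjusted p = 0.0701), the ephrin receptor epha8.L (1.07, adjusted p = 0.0819), the forkhead factor foxk2 (1.82, adjusted p = 0.0953), and twsg1.S, a regulator of BMP signalling (1.01, adjusted p = 0.0996). tubgcp2.L, spats2.L and braf.S had log2 changes of 1.39, 1.16 and 0.93. For tubgcp2.L, not well above background in control eyes, the difference in the main values is at least 1.74-fold. Over the alternatives the log2 change of tubgcp2.L ranged from 0.27, which is below that bound, to 1.52. Below their control level were frzb, a secreted Wnt antagonist (-2.07, SE 0.26, adjusted p = 0.0698), and scamp2.L, eif2b2.L, sult6b1.1.L and ogn.L, with log2 changes of -1.13, -0.89, -1.13 and -1.09. cct4.L, slc25a17.S, slc30a9.S and rassf6.L had log2 changes of -0.63, -0.61, -0.57 and -0.93, each with an adjusted p of 0.121. With an intensity trend and robust variance estimates, and with normexp, farp2.S, spop.S, foxk2, frzb and eif2b2.L passed the threshold. cct4.L passed with the intensity trend only (limma adjusted p = 0.0405), and frzb also passed without control replicate 1 (limma adjusted p = 0.0469).

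Markers of pigment, lens, retinal neurons and glia were lower as groups in Ezh2 morpholino eyes by camera with a preset correlation of 0.01, though no single gene of these lists passed the test over all probes. The lists are named by textbook use of their genes, and whether these cell types were present at stage 27 was not tested. Pools of dissected eyes were measured, so which cells gave these signals is not known. The pigment epithelium and melanin list had a median log2 change of -0.33 over 21 genes (17 lower, adjusted p = 6.81e-05), the lens list of -0.54 over 16 genes (14 lower, adjusted p = 0.00198), the retinal neuron list of -0.29 over 41 genes (35 lower, adjusted p = 6.81e-05) and the Müller glia list of -0.15 over 22 genes (15 lower, adjusted p = 0.0232). With an estimated correlation all 4 calls were lost (adjusted p = 0.614 for each), and fry gave adjusted p-values of 0.197, 0.623, 0.623 and 0.388. The retinal neuron median was -0.09 without Ezh2 morpholino replicate 1 and the lens median -0.27 without control replicate 2, both still called, and the Müller glia call was lost without Ezh2 morpholino replicate 3 (-0.13) or control replicate 2 (-0.12). The retinal neuron list's mean was -0.66 in Ezh2 morpholino replicate 1 and 0.25 in replicate 4, and without replicates 1 and 3, which stood apart, its median was -0.05 and that of the Müller glia list -0.04 (adjusted p = 0.432 for both). The pigment and lens lists were still called without these arrays, with medians of -0.20 and -0.58 (adjusted p = 0.00936 and 0.00182). The lens list was lowest in replicate 2, with a mean of -0.91.

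In the pigment list 4 genes were lower adjusted over the list alone. They were tyrp1.L, dct.L and tyr, the enzymes of melanin synthesis, and pmel.L, which forms the fibrils of the melanosome. Their log2 changes were -2.02, -1.74, -1.50 and -1.43, and dct.L, for example, went from 12.24 ± 0.58 to 10.49 ± 0.93 (SD, n = 4 each, adjusted p = 0.192 over all probes). The S copy of pmel lay at -1.32 and slc45a2.L, a melanosome transporter, at -1.33. The visual cycle gene rpe65 lay at 0.08 and 0.10 in its L and S copies. In the lens list no gene passed, adjusted over the list alone or over all probes. The fibre cell membrane gene lim2.L lay at -2.20 (SE 0.81), the crystallins crybb1.S and cryba4.S at -2.36 and -1.08, and the lens channel mip.S at 0.28. Control morpholino replicate 2 carried part of this difference, with a list mean of 1.52 where the other control arrays lay between -0.08 and 0.21.

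No retinal neuron gene passed adjusted over the list alone. The inhibitory neuron genes gad2.L and slc32a1.S, for GABA synthesis and its loading into vesicles, lay at -0.96 and -1.07, and the axon growth genes gap43.S and l1cam.S at -0.44 and -0.55. Of the 41 genes 35 lay lower and 6 higher. Among the higher were rbpms.L at 0.49 and pou4f2 at 0.41 (limma adjusted p = 0.347 and 0.363). In the Müller glia list apoe.L and rlbp1.L were lower and nfix.L was higher adjusted over the list alone. apoe.L, an apolipoprotein, had a log2 change of -1.47, rlbp1.L, a retinoid-binding protein of glia and pigment epithelium, of -1.26, and nfix.L, a transcription factor of gliogenesis, of 1.30. The photoreceptor list did not pass (33 genes, median -0.02, from -0.11 to 0.09 over the alternatives, camera adjusted p = 0.563). The phototransduction genes sag.L and grk1 lay at 1.25 and 1.06, with adjusted p-values of 0.203 and 0.208. grk1 was dim, well above background on 2 of the 4 control arrays, and ranged from 0.49 to 1.37 over the alternatives. Members of the list went both ways (16 higher, 17 lower), with pde6g at 0.48 in its L copy and -0.66 in its S copy.

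**Figure D2:**
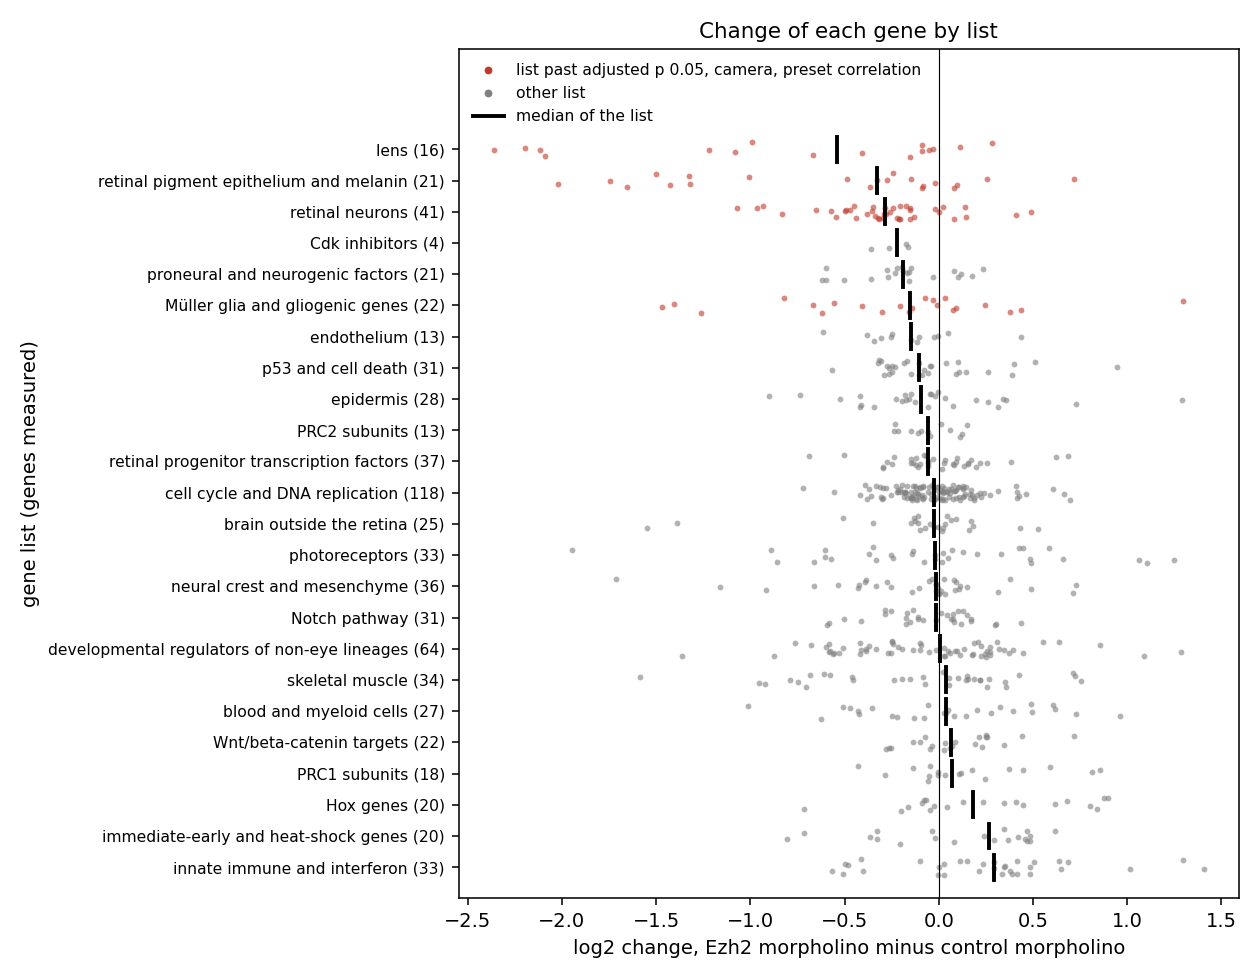
Each point is 1 gene's log2 change, Ezh2 morpholino minus control morpholino, in the 24 gene lists, with the number of genes measured in parentheses and a black bar at the list's median; red lists passed an adjusted p of 0.05 by camera with the preset correlation. The medians run from -0.54 for lens to 0.30 for innate immune and interferon genes.

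**Figure D3:**
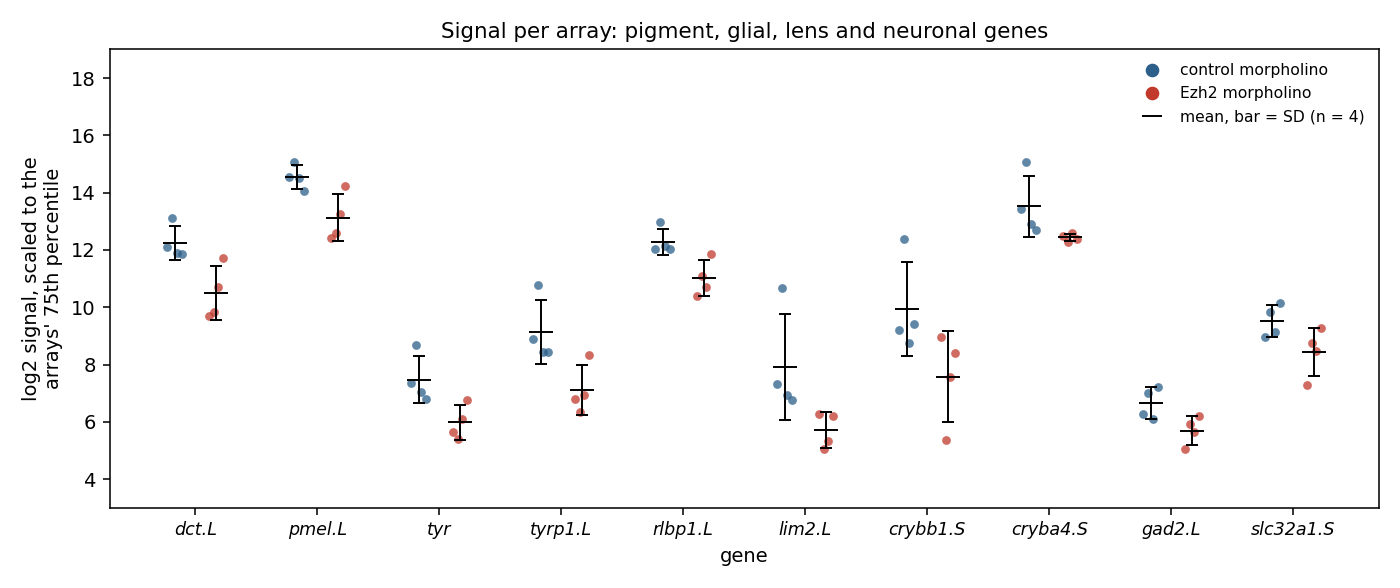
Each point is the log2 signal of 1 array, scaled to the arrays' 75th percentile, for pigment, glial, lens and neuronal genes, with the mean and SD of the 4 control (blue) and 4 Ezh2 morpholino (red) arrays. The dct.L means are 12.24 and 10.49, and in lim2.L 1 control array at 10.66 stands above the other control arrays at 6.76 to 7.32.

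Genes of proliferation and neurogenesis, which the title names, did not pass as groups in the main values. None of the 118 cell cycle and DNA replication genes passed the test (median log2 change -0.03, or 0.003 with quantile normalization, camera adjusted p = 0.101), nor any adjusted over the list alone. The list passed with normexp, in the authors' value table and without control replicate 4, each time lower (adjusted p from 0.000763 to 0.865 over the alternatives). In the main values, random lists of the same brightness had a median of -0.038 (95% range -0.087 to 0.012). The cell cycle median of -0.025 lay inside that range, so the list was not lower than genes of its brightness. The kinetochore motor cenpe.L lay at -0.56 and the spindle checkpoint kinase bub1b.L at -0.36, while the phosphatase cdc25b.L lay at 0.70 and the centriole kinase plk4.L at 0.43. All 4 measured Cdk inhibitors had negative log2 changes and none passed. cdknx.L (p27Xic1, the frog Cdk inhibitor of cell cycle exit) lay at -0.36 (SE 0.24, adjusted p = 0.497), and cdkn1a.L, cdkn2d.S and cdkn1b.S at -0.27, -0.17 and -0.16. The probes of cdkn1b.S disagreed: a dimmer probe gave 1.03 (adjusted p = 0.269). A further probe of cdknx.L gave 0.03. The list's median was -0.22 (camera adjusted p = 0.137), or -0.07 without Ezh2 morpholino replicate 1. Without replicate 3 it was -0.37 and the list passed (adjusted p from 0.0444 to 0.614 over the alternatives).

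The proneural list had a median of -0.19 over 21 genes with 16 lower (camera adjusted p = 0.0849), and no member passed. Over single arrays left out its median ranged from -0.26 to -0.08. The neurogenic factors neurog2.S, neurod4.L and neurod1.S lay at -0.27, -0.60 and -0.50. The call of this list passed with normexp, with the mean over a gene's probes, and without Ezh2 morpholino replicate 3 or 4 or control replicate 4. The 37 genes of the retinal progenitor list, most of them transcription factors, had a median of -0.06, from -0.15 to 0.06 over the alternatives (camera adjusted p = 0.317), and passed as a list without control replicate 4. Among these genes tbx3.L, the receptor gene fzd5.S and six3 lay at 0.62, 0.69 and 0.38, and zic2.S at -0.30 (dimmer probes at 0.05 and 0.04), none past the threshold. The 22 Wnt/beta-catenin targets had a median of 0.07, or -0.03 in the authors' value table (camera adjusted p = 0.563), with myc.S at 0.72 (adjusted p = 0.258), myc.L at 0.44 and lef1.L at 0.35. Over single arrays left out myc.S ranged from 0.48 to 0.86 and myc.L from 0.22 to 0.55. The list names tbxt by its old symbol t, so this gene was not matched and is not counted. Its L and S copies lay at 1.65 and 0.59 (limma, unadjusted p = 0.0139 and 0.0263), neither past the adjusted threshold. The 31 Notch pathway genes had a median of -0.01, from -0.11 to 0.05 over the alternatives (camera adjusted p = 0.19), and passed with normexp, with the Notch effectors hes5.10.L and hes5.2.S at -0.59 and -0.58.

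Hox genes, known targets of PRC2, had a median log2 change of 0.18 over 20 genes, with 12 higher (camera adjusted p = 0.178). The median was 0.02 with quantile normalization, 0.06 and 0.09 without control replicate 1 or Ezh2 morpholino replicate 1, and 0.34 without Ezh2 morpholino replicate 2. Adjusted over the list alone 4 were higher, and over all probes none. These were hoxc8.S (0.90, SE 0.14, adjusted p = 0.106 over all probes), hoxb7.S (0.88), hoxc12 (0.81) and hoxb7.L (0.61). With normexp the list passed. Of 18 genes of Polycomb repressive complex 1, 3 were higher and 1 was lower adjusted over the list alone, and none over all probes. cbx8.L lay at 0.86, phc1.S at 0.81, cbx8.S at 0.59 and ring1 at -0.43, and the list did not pass (median 0.07, or -0.03 in the authors' value table, camera adjusted p = 0.288). The 64 developmental regulators of non-eye lineages had a median of 0.01 and a mean of -0.05, and a median of -0.09 with quantile normalization and 0.12 with normexp (camera adjusted p = 0.317), with pax8.L and meox2.L at 0.86 and 0.64. A dimmer meox2.L probe gave -0.41 (SE 0.52). The gene tbxt, listed under its old symbol t, was not matched to this list either (L copy 1.65, S copy 0.59).

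Innate immune and interferon genes had a median of 0.30 over 33 genes, 24 of them higher (camera adjusted p = 0.101), and no member passed. The list passed without control replicate 4. The RNA sensor kinase eif2ak2.L lay at 0.68, nfkb2.S at 0.51, socs1.S at 0.49 and myd88.S at -0.40. The p53 and cell death list, which a toxic morpholino would raise, had a median of -0.10 over 31 genes (camera adjusted p = 0.137) and passed, lower, with normexp and without Ezh2 morpholino replicate 3, with apaf1.L at 0.94 and ccng1.S at -0.25. The median of that list ranged from -0.20 to -0.03 over the alternatives. Immediate-early and heat-shock genes had a median of 0.27 over 20 genes (camera adjusted p = 0.985), or 0.08 without Ezh2 morpholino replicate 3 and -0.02 without replicates 1 and 3, with atf3.L at 0.47 and hmox1.L at -0.36.

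Markers of tissues next to the eye did not pass as groups in the main values. The neural crest and mesenchyme list passed, lower, in 6 of 20 alternatives: with normexp, with no filter, with the mean over a gene's probes, and without Ezh2 morpholino replicate 1 or 2 or control replicate 3 (adjusted p from 0.00886 to 0.614). Endothelium passed, lower, with normexp and without Ezh2 morpholino replicate 4 or control replicate 4 (adjusted p from 0.00139 to 0.667), and brain with normexp and without Ezh2 morpholino replicate 2 (adjusted p from 0.0321 to 0.982). No direction held over all alternatives in these lists. The medians ranged from -0.07 to 0.15 for skeletal muscle, -0.07 to 0.17 for blood, -0.22 to 0.14 for epidermis, -0.11 to 0.04 for neural crest and mesenchyme, -0.31 to 0.19 for endothelium and -0.14 to 0.27 for brain. Single arrays left out turned each of the 6, and without Ezh2 morpholino replicates 1 and 3 brain lay at 0.27, endothelium at 0.19 and epidermis at 0.14. Skeletal muscle genes had a median of 0.04 and a mean of -0.12 over 34 genes (camera adjusted p = 0.312), and adjusted over the list alone 2 were higher and 3 lower. Among them myl2.S lay at 0.75 and myf6.L, not well above background in Ezh2 morpholino eyes, was at least 1.25-fold lower, though at a log2 change of 0.17 with normexp. The S copy of myf6 went the other way, at 0.42 (limma, unadjusted p = 0.036). Blood and myeloid genes had a median of 0.04 over 27 genes (camera adjusted p = 0.563), with the globins hbz.L and hbg2.L at 0.96 and 0.73, both higher adjusted over the list alone. The probes of hbz.L disagreed: a dimmer one, well above background on 1 of the 4 Ezh2 morpholino arrays, gave -1.58 (SE 0.71, adjusted p = 0.34). Brain genes had a median of -0.02 over 25 genes (camera adjusted p = 0.222), and adjusted over the list alone eomes.L was lower (-1.39) and irx2.L higher (0.53). Whether the genes of the brain list are also active in the eye was not tested, and barhl1 was entered in the retinal neuron list as well. Neural crest and mesenchyme genes had a median of -0.01 over 36 genes (camera adjusted p = 0.0963), with lum.L at -1.16 and col3a1-a at 0.71. Epidermis genes lay at -0.09 over 28 genes (camera adjusted p = 0.317), with krt62.S at 0.73 and the cadherin gene cdh1 at -0.74. krt62.S was dim, well above background on 2 of the 4 control arrays. Endothelium genes lay at -0.15 over 13 genes (camera adjusted p = 0.101), with pecam1.L at 0.44 and erg.L at -0.38.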

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

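The tests in this part were chosen after the results they concern were seen, except the test on second probes over 994 genes and that on probes sharing sequence with fzr1.L, which were written down before.

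Among 256 groups of 4 arrays (named genes, list means and array measures), 14 held 1 array far from the other 3, where chance flags about 1 in 20 groups, or 12.8. In Ezh2 morpholino replicate 1, phf1.L had a log2 signal of 7.28 (others 7.70 to 7.73), hoxb7.L of 7.42 (others 7.88 to 7.91), and the cell cycle list a mean of -0.059 (others 0.00 to 0.01). In Ezh2 morpholino replicate 2, ogn.L lay at 9.38 (others 8.74 to 8.82). In Ezh2 morpholino replicate 3, grk1 lay at 3.16 (others 4.28 to 4.45), the Polycomb repressive complex 1 list at 0.22 (others 0.03 to 0.04) and the immediate-early and heat-shock list at 0.43 (others -0.12 to -0.04). In Ezh2 morpholino replicate 4, suz12 lay at 12.06 (others 11.89 to 11.91). Among control arrays, replicate 1 stood apart in eed.L at 12.45 (others 12.67 to 12.68) and cct4.L at 15.49 (others 15.65 to 15.68), and replicate 4 in jarid2-b at 12.81 (others 12.37 to 12.40). Control replicate 2 stood apart in lim2.L at 10.66 (others 6.76 to 7.32), rlbp1.L at 12.96 (others 12.02 to 12.14) and l1cam.S at 9.84 (others 9.03 to 9.17), so 3 eye markers were high in the same pool.

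The number of probes that differed between the groups exceeded that of every other split of the arrays. Of the 35 splits of the 8 arrays, 1, the real one, gave as many as 12 called probes (highest other 9). The same 1 split alone gave as many as 5531 probes at an unadjusted p under 0.05 (highest other 4347). A share of 1 in 35 is the smallest that 8 arrays can give, and the counts had been seen before. A chance split of the arrays is thus less likely for both counts but not excluded. An effect of each probe's own sequence on 1 slide was argued against as the whole cause: of 994 genes with a probe at an unadjusted p under 0.05 and another, non-overlapping probe, 81% had the other probe on the same side (95% interval 78.4% to 83.4%). The other probe's change was smaller, with a median ratio of 0.514 to the first probe's. It also had an unadjusted p under 0.05 in 234 genes on the same side and in 8 on the opposite side. A difference between slides that acts on whole samples could not be separated from the morpholino, since each slide held 1 group. Spike-in RNA lay at 0.32 ± 0.30 (SD, n = 4) on the Ezh2 morpholino slide and 0.03 ± 0.17 on the control slide (log2 over the 75th percentile, exact permutation p = 0.2), and the effect of the Ezh2 morpholino stays open beside it. Spike-in RNA was highest in Ezh2 morpholino replicates 1 and 3 (0.651 and 0.482), which stood apart on the first principal component. Replicates 2 and 4 (0.165 and -0.01) lay within the control range of -0.213 to 0.192. The slides did differ in their raw scans. The median local background lay at 24 to 25 on the Ezh2 morpholino slide and 26 to 28 on the control slide. The dark offset in the file headers was 5.97 and 5.4. What these differences do to the processed signal was not tested.

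The fzr1.L probe rose without the other probe of the gene. A change of the whole transcript would move both, and the other probe's log2 change of -0.004 (SE 0.14) lay 16.6 standard errors of the difference below the called probe's. Of the other probes on the array, 0 shared 16 or more bases in a row with it, so a related transcript measured elsewhere on the array was not found, and one without a probe may still be the source. A different transcript end, a sequence variant between the parents of the pools and an effect of the morpholino on splicing or stability were not tested and cannot be told apart here.

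The pigment, lens and retinal neuron lists were lower, but of the 35 splits of the arrays 25 called at least as many lists as the 4 of the real split (highest other 12), so a chance split of the arrays cannot be excluded for the number of lists called with the preset correlation. Taken singly, the lens list's mean lay lower on all 4 Ezh2 morpholino arrays (-0.91 to -0.14) than on all 4 control arrays (-0.08 to 1.52; exact permutation p = 0.0286, the smallest that 8 arrays can give, adjusted p = 0.229 over 24 lists, which this p alone cannot pass), and the exact p was 0.0571 for pigment (adjusted p = 0.274) and 0.229 for retinal neurons (adjusted p = 0.61). A trend with brightness was argued against, because random lists of the same brightness had a median log2 change of 0.052 (95% range -0.03 to 0.13) where the 78 genes of the 3 lists had -0.29. Such random lists were drawn as independent genes, so their 95% ranges are too narrow for genes that vary together. A lower share of eye tissue in the Ezh2 morpholino pools stays open. The progenitor list minus the 3 lists lay at 0.28 ± 0.14 (SD, n = 4) in Ezh2 morpholino eyes and -0.28 ± 0.43 in controls (exact permutation p = 0.0571). The 6 lists named for non-eye tissues had medians of -0.15 to 0.04 that changed sign with single arrays left out. A lower share would raise these 6 lists if their genes are less active in the eye than outside it, which was not tested. An effect of the Ezh2 morpholino on differentiation of these cell types may also account for the lower lists and was not tested apart from these values.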

How the results depend on the processing

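Of 1814 alternative values of the 101 named genes, 1784 kept their side of the threshold and the direction of any call, 18 lost the call (10 of dph1.L and 8 of adhfe1.S), 12 gained it and 0 reversed a call; 15 values, none of them a call, changed sign. Of 480 values of the 24 lists, 10 lost the call, 27 gained it and 0 reversed, with 63 medians of the other sign. ezh2.L ranged from -0.33 to -0.14 and ezh2.S from -0.15 to 0.04, with no call. Against 11 probes higher and 1 lower, the count lower was 4 with normexp, 2 with no filter and 4 with an intensity trend and robust estimates (12, 13 and 16 higher), and the count higher was 7 with probes above background on all 8 arrays. The replicate block left 2 higher and 0 lower. Same-numbered samples did not deviate together (r from -0.14 to 0.09), only Ezh2 morpholino replicate 1 correlated best with its own number, and the numbers are taken as names. Leaving out 1 array gave 5 to 9 higher and 0 to 2 lower. The lowest count higher, 5, came without Ezh2 morpholino replicate 3 or control replicate 4, and 6 came without control replicate 1 or 2, 7 without Ezh2 replicate 2 or control replicate 3. Without Ezh2 morpholino replicates 1 and 3, chosen after seeing the data, 3 were higher and 0 lower, on 6 arrays; the retinal neuron list (-0.05) and the Müller glia list (-0.042) lost their calls. The Müller glia call was also lost with quantile normalization (-0.11), with array weights (-0.14) and without Ezh2 replicate 3 (-0.13) or control replicate 2 (-0.12), with a range over single arrays left out of -0.20 to -0.12. With the estimated correlation, which changes the test and not the values, the calls of retinal neurons (-0.29), Müller glia (-0.15), pigment epithelium (-0.33) and lens (-0.54) were lost. Otherwise the cause was not tested. Over single arrays left out the medians ranged from -0.38 to -0.09 for retinal neurons, -0.41 to -0.28 for pigment epithelium and -0.73 to -0.27 for lens, all still called. Normexp called 13 lists. Slide and scan date blocks were not run, since each slide holds 1 group. Signal over background limits probes dimmer than the filter.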

Other observations

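The homeologs gave a view of which differences recur in both copies of a gene; the genes in this paragraph were chosen after their values were seen. Of 1749 gene pairs with both copies measured, 70 had both at an unadjusted p under 0.05, and 64 of these went the same way. Of the 410 pairs with at least 1 copy at such a p, 307 went the same way. Across all 1749 pairs, which are not independent replicates, Pearson's r of the changes was 0.379 and Spearman's rho 0.401. Lower in both copies were ntf3, a neurotrophin (log2 changes -1.08 and -1.24 for L and S), the T-box factor eomes (-1.39 and -1.55), pmel (-1.43 and -1.32), cav1 (-0.49 and -0.65) and the arginine methyltransferase prmt5 (-0.39 and -0.47). Higher in both were the kinase stk10 (1.02 and 1.20), the Polycomb gene cbx8 (0.86 and 0.59), hoxb7 (0.61 and 0.88), vegfa, an angiogenic growth factor (0.53 and 0.76), and szl, a secreted regulator of BMP signalling (2.60 and 0.53). The caveolae gene cav2 went apart (-0.66 and 1.28). None of these passed the adjusted threshold, and a probe may take up signal from both copies, which the share of 81% for probes of 1 gene does not exclude.

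The tests on Hox genes, regulators of other lineages and innate immune genes were chosen after the medians of these lists were seen. Higher Hox signal may come from release of genes that PRC2 represses. The Hox list's mean lay at 0.12 ± 0.10 (SD, n = 4) in Ezh2 morpholino eyes and -0.12 ± 0.14 in controls (exact permutation p = 0.0571, adjusted p = 0.274 over 24 lists). Random lists of the same brightness had a median change of 0.16 (95% range -0.02 to 0.33), close to the Hox median of 0.18, since dim probes lay higher as a whole, so the list as a whole does not stand apart from probes of its brightness. A release of regulators of non-eye lineages as a class stays open: their median of 0.005 lay below the 0.02 to 0.21 of brightness-matched lists, which goes against it, but 32 members lay higher and 32 lower and the median was 0.12 with normexp, so it is not excluded.

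The higher innate immune list has no explanation that these values decide. Its mean lay at 0.12 ± 0.11 (SD, n = 4) against -0.12 ± 0.04, all 4 Ezh2 morpholino arrays above all 4 controls (exact permutation p = 0.0286, the smallest that 70 orders of the arrays can give, adjusted p = 0.229 over 24 lists). The median of 0.30 lay above the brightness-matched range of -0.04 to 0.22. That range leaves out how genes of a list vary together, so lying outside it decides nothing alone. The immediate-early and heat-shock list also lay above its range (median 0.27, range -0.13 to 0.15), at an exact permutation p of 0.714. The lens list and the Polycomb repressive complex 1 list reached the same exact permutation p of 0.0286 as the innate immune list. The mean of the Polycomb list lay at 0.08 ± 0.09 (SD, n = 4) against -0.08 ± 0.03 in controls. Its median of 0.07 lay inside its brightness-matched range of -0.13 to 0.18. With a smallest p of 0.0286, 1 list cannot pass a correction over 24 lists, so the adjusted p decides nothing. The innate immune list holds members that go both ways (24 higher, 9 lower). A response to injection that differs between the morpholinos, an effect of the Ezh2 morpholino on these genes and a difference between the slides would each give these values, and they cannot be told apart here.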
